A study of Mus musculus with 25 samples.

How the data were processed

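The data came from 25 Affymetrix Mouse Gene ST arrays of cells sorted from the Peyer's patches of female C57BL/6 mice aged 6 to 8 weeks, per the labels. The 7 groups were untreated CD11b+ conventional dendritic cells (cDC, 5 arrays), untreated CD4- CD8α- CD11b- cDC (DN cDC, 3), untreated CD8α+ cDC (3), untreated TIM-4- LysoMac (3), untreated TIM-4+ LysoMac (3), and CD11b+ cDC (3) and CD8α+ cDC (5) taken 9 h after oral R848, a TLR7 ligand. The titles of the 8 R848 samples also carry the words steady state, and their treatment was taken from the other labels. Per the labels' protocols, each replicate pooled 42 mice, the patches were digested with collagenase and DNase, CD11c+ cells were enriched on magnetic beads and then sorted, and 2 to 20 ng of RNA were amplified. The series design calls the replicates independent. The labels do not say that a replicate number marks a shared pool or day, so the groups were compared as unpaired, with the number as a block in an alternative. Per the labels, cDC were sorted as CD11c-high and MHC class II positive, with SIRPα on CD11b+ and DN cDC but not on CD8α+ cDC. LysoMac were sorted as CD11c-high, MHC class II low, SIRPα+, BST2+ and CD4+.

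Per the submitters' processing notes, the authors computed the deposited values as log2 signals with RMA in Affymetrix Expression Console 1.4.1. Whether all arrays were normalized together, and the genome build of the probe annotation, are not given in the sources used here. The arrays had medians of 4.33 to 4.67 on the log2 scale, and every array correlated at 0.989 or higher with the rest of its group.

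The columns of the deposited table did not share one row order. The arrays fell into 3 sets: the 14 untreated CD11b+, DN and LysoMac arrays, the 3 untreated CD8α+ arrays, and the 8 R848 arrays. Correlations across rows were at least 0.938 within a set and between 0.075 and 0.225 across sets. The deposited row names fitted the R848 arrays, in which both transcript clusters of 999 genes with more than 1 cluster correlated at 0.83, against 0.144 and 0.081 in the other sets. The rows of those sets were therefore aligned to the R848 arrays. A monotone alignment found by dynamic programming kept the row order and allowed rows to be passed over. The alignment compared mean levels, those of untreated with R848 CD11b+ cDC for one set and of untreated with R848 CD8α+ cDC for the other. These pairs are the ones later tested for the R848 responses, so the matching can favour rows with small responses. It covered the 28939 rows from the first annotated row on and left out the 6617 rows before it. A row was accepted where 3 alignment settings gave the same partner, where it lay inside a run without a gap, and where its neighbours correlated across both sets. Of the aligned rows, 22838 (78.9%) were accepted for the untreated CD11b+, DN and LysoMac set and 23212 (80.2%) for the untreated CD8α+ set. Accepted rows correlated with the R848 arrays at 0.966 and 0.947, values that the matching itself raises. With the rows rolled out of place as a control, 104 and 28 rows were accepted. After alignment the clusters of one gene correlated at 0.827 over 751 genes and at 0.824 over 757 genes, against 0.814 and 0.842 for the same rows of the R848 arrays. Both untreated sets, aligned to each other directly, gave the same partner for 99.86% of 18684 rows. Tested on simulated data with 500 rows taken out and put in, at most 0.904% of accepted rows had a wrong partner in 5 runs, and at most 0.471% had one whose value lay over 1 log2 unit off. The simulated profiles came from CD8α+ and CD11b+ cDC after R848, inside 1 array set. The real matching crossed sets, so its error rate could be higher than these values. A rule of this kind can still lose genes that differ strongly, since a large difference breaks the fit of a row. In the simulations 76.5% to 80.1% of the changed rows were accepted, against 81.5% or more of all rows.

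Rows with 1 gene symbol in the platform annotation were kept, and a gene took the value of the transcript cluster present in most arrays and, among those, with the highest mean. The presence condition was added after the row order was found. This left 19938 genes, of which 14519 had a value in all 3 array sets. Negative control genes (olfactory, vomeronasal and taste receptors, keratins, keratin-associated proteins, beta-defensins and crystallins, chosen after the data were seen) were used to look for wrong rows. Over the comparisons, at most 2 of 1021 such genes differed by more than 4-fold, in LysoMac against cDC and in both comparisons of untreated CD8α+ cDC with the other cDC. In LysoMac against cDC, 366 of the 13498 other genes did so. A slip by a few rows would go unseen where such a gene lies beside others of its family, which was not checked. The control can thus miss local errors. Between 2 clusters of one gene, the log2 differences correlated at 0.435 (TIM-4+ against TIM-4- LysoMac) to 0.827 (LysoMac against CD11b+ and DN cDC). A second cluster did not show the difference of Armc4, Trank1, Atxn1 and Slc16a9, and these genes are not named among the results except once, with that fact.

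One limma 3.58.1 model (R 4.3.3) with a mean per group was fitted over all arrays. Empirical Bayes variances were shared over all genes, tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. SE is the moderated standard error of a difference. The comparisons, their tests, the gene lists, the rule for named genes and the first alternative settings were set before the data were examined, and further settings were added afterwards. The comparison of CD8α+ with CD11b+ cDC after R848 and that of LysoMac with CD11b+ and DN cDC alone were added afterwards, because each lies inside 1 array set. Comparisons across sets (those of untreated CD8α+ cDC with other groups and both R848 responses) had set and group confounded, and no batch term could be fitted for them. The named genes were the 10 with the largest difference in each direction among called genes with no overlap between the arrays of the groups (for the difference of responses, among all called genes), the called members of each described list with the largest differences (up to 4, plus up to 2 of the smaller direction), for a list with no called member up to 2 with the highest mean, and the sort markers. Antigen receptor segments and predicted genes were counted and not named. Naming was further limited, after the data were seen, to rows that passed a stricter match, except for the sort marker Cd8a in the R848 response of CD8α+ cDC.

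Gene lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated per list, both adjusted over the lists of a comparison. The 35 lists were interferon-stimulated genes, interferon-gamma-inducible GTPases, dendritic cell maturation and co-stimulation, cytokines, chemokines, chemokine receptors and trafficking, cDC1 and cDC2 signatures, a macrophage signature, lysosome and hydrolases, apoptotic cell uptake, MHC class II and class I presentation, Toll-like receptors and innate sensors, retinoic acid and IgA-related factors, antimicrobial factors, cell cycle, glycolysis, cholesterol synthesis, unfolded protein response, dissociation and immediate early genes, glucocorticoid-induced genes, circadian clock genes, sort markers, and markers of B cells, plasma cells, T cells, NK cells and ILC, plasmacytoid DC, neutrophils, monocytes, mast cells and basophils, epithelium, stroma and endothelium, and erythroid cells. Counts of called members refer to all genes tested unless they are given as adjusted over the list alone. The position of an array between CD8α+ and CD11b+ cDC was the slope through the origin of its difference from the CD8α+ mean on the difference between both means, with an exact two-sided permutation test.

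The pipeline was tested on simulated data with the spread of these arrays. Of 100 genes changed 2-fold, it recovered 98 for LysoMac against cDC, 79 for TIM-4+ against TIM-4- LysoMac, 92 for CD8α+ against CD11b+, 93 for DN against CD11b+, 92 for DN against CD8α+, 91 and 96 for the R848 responses of CD11b+ and CD8α+ cDC, 81 for the difference of the responses and 97 for the subsets after R848. Of genes changed 4-fold, 98 to 100 of 100 were recovered, and 5 to 19 unchanged genes were called. These counts reflect the spread of the arrays and were not a test of an offset between array sets or of wrongly matched rows. They thus give no rate of false calls for comparisons across sets. In the real R848 response of CD8α+ cDC, 56.7% of the dimmest genes were called, against 56.8% of all genes. There 11.072% of the negative control genes were lower, with a median of 0.208. Alternatives covered the scaling of the arrays (a common median, cyclic loess, and quantile normalization of the genes with a value in all 3 sets), dim genes, the choice of transcript cluster, arrays in the fit, the variance model, array weights, a replicate block, leaving out each array, a size threshold, the rule for accepting rows, and untreated CD11b+ replicates 4 and 5. Genes with several symbols per row (1621 rows) and rows without a gene (12146) were not used. Figures and checks used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.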

Results

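The arrays compared macrophages and dendritic cells of the Peyer's patch, the lymphoid tissue of the small intestine that takes up gut antigen. Untreated LysoMac from mice in the steady state were set beside 3 cDC groups, TIM-4+ beside TIM-4- LysoMac, and the cDC groups beside each other. CD11b+ and CD8α+ cDC were also compared 9 h after mice were given R848 by mouth. Differences are in log2 units with their SE, and genes were called with limma. Of 19938 genes, 14519 could be compared across all groups and 16549 among untreated CD11b+, DN and LysoMac groups.

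**Figure D1:**
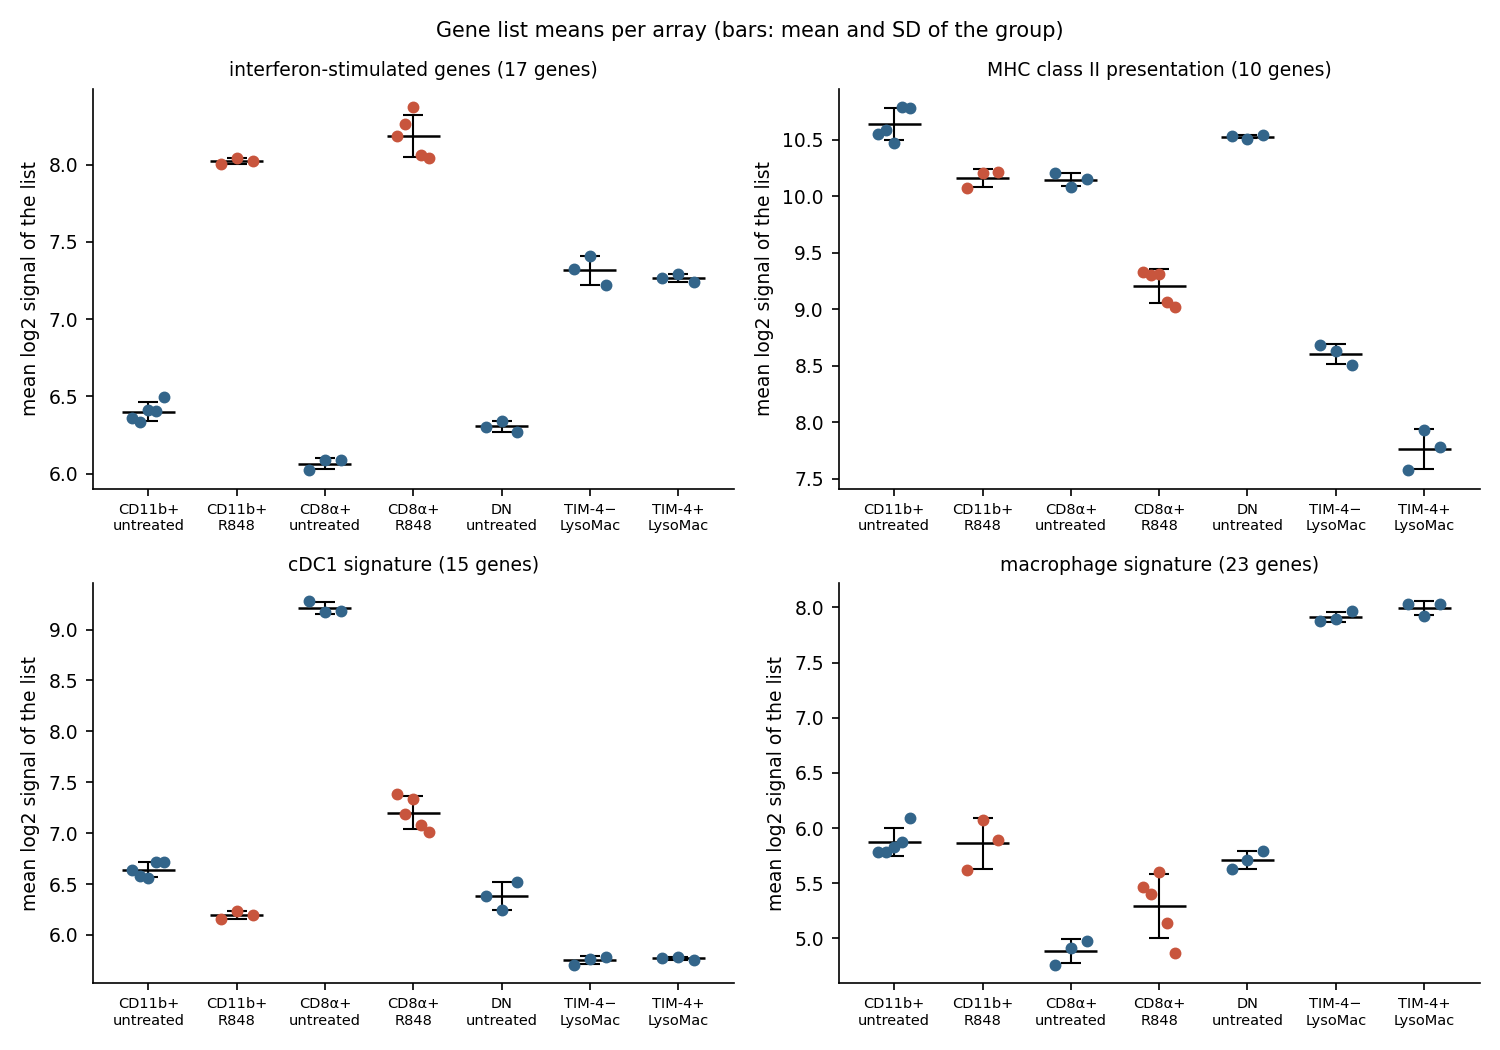
Mean log2 signal (y axis) of 4 gene lists in each of the 25 arrays by group (x axis), one point per array, untreated in blue and R848 in red, with bars for the mean and SD of the group. The interferon-stimulated genes averaged 8.02 in CD11b+ cDC after R848 and 6.40 in untreated CD11b+ cDC, and the macrophage signature averaged 7.91 in TIM-4- LysoMac and 5.87 in untreated CD11b+ cDC.

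LysoMac (6 arrays) differed from cDC (11 arrays) by a macrophage and lysosome program in one direction and by migration and MHC class II genes in the other, the latter in the direction of the sort. Among the genes with the largest differences were Atp6v0d2, a subunit of the proton pump of lysosomes (6.23 ± 0.11), Cp, the copper carrier ceruloplasmin (6.20 ± 0.15), Acod1, the enzyme that makes itaconate (6.19 ± 0.29), and the scavenger receptor Msr1 (5.63 ± 0.25), all higher in LysoMac. Genes lower in LysoMac included Itgae, the integrin chain CD103 (-5.63 ± 0.19), Alox5ap, which is needed for leukotriene synthesis (-5.11 ± 0.18), and Flt3, the receptor for the growth factor of dendritic cells (-4.91 ± 0.07). Of the sort markers, Cd4 (5.18 ± 0.11), Itgam (2.24 ± 0.13) and Timd4 (2.05 ± 0.20) were higher in LysoMac, while Itgax was 0.05 ± 0.10 (adjusted p = 0.716). The Timd4 value averages both LysoMac groups and does not show a higher level in TIM-4- cells, since Timd4 was far higher in TIM-4+ cells. In the LysoMac gate, SIRPα and BST2 were selected per the labels, and against CD11b+ and DN cDC alone Bst2 was higher by 2.36 ± 0.13 and Sirpa by 1.32 ± 0.19.

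The macrophage signature had 15 of 23 measured members higher in LysoMac and 0 lower (16 and 0 adjusted over the list alone). Mertk, a receptor for dying cells, was higher by 5.11 ± 0.12, Cx3cr1 by 4.78 ± 0.16 and Fcgr3 by 4.70 ± 0.25. Of 24 lysosome and hydrolase genes 23 were higher and 1 was lower, with the same counts adjusted over the list alone. Among them were the proteases Ctsd (4.74 ± 0.23) and Tpp1 (3.21 ± 0.09), and the exception was the protease Lgmn (-1.12 ± 0.15). Antimicrobial factors had 9 of 11 members higher and 1 lower (10 and 1 over the list alone). Lyz1, a lysozyme, was at 3.90 ± 0.49 and Pglyrp1, which binds bacterial cell walls, at -4.78 ± 0.16. Interferon-stimulated genes were higher in untreated LysoMac for 13 of 17 members and lower for 1 (14 and 1 over the list alone). They included Irf7, the transcription factor that amplifies type I interferon (2.31 ± 0.10), and Oas1a (1.97 ± 0.14). All 7 measured interferon-gamma-inducible GTPases were higher (7 over the list alone), Gbp3 by 2.85 ± 0.09.

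MHC class II presentation genes were lower in LysoMac for 8 of 10 members and higher for 1 (the same over the list alone). LysoMac were sorted as MHC class II low and cDC as positive per the labels, so the gate can set this direction. Among the lower genes were H2-Ob (-4.34 ± 0.12), Ciita, the switch of class II transcription (-4.03 ± 0.08), and H2-Oa (-3.64 ± 0.16). The cDC1 signature had 10 of 15 members lower and 3 higher (11 and 3 over the list alone). Chemokine receptor and trafficking genes had 11 of 16 lower and 3 higher (the same over the list alone). Ccr7, the receptor that leads dendritic cells to T cell zones, was at -3.80 ± 0.21. Cell cycle genes were lower for 23 of 25 members and higher for 1 (the same over the list alone), such as Top2a (-1.79 ± 0.17) and Mcm6 (-1.76 ± 0.17). Dissociation and immediate early genes were lower for 11 of 14 and higher for 1 (the same over the list alone), with Nr4a1 at -4.30 ± 0.18. Among markers of other cells, NK cell and ILC markers had 2 of 8 lower and epithelial markers 3 of 13 lower (list adjusted p = 0.0268 each, lost at adjusted p = 0.15 and adjusted p = 0.546 with an estimated correlation, the epithelial call also after cyclic loess at adjusted p = 0.0605).

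In all, 6187 of 14519 genes were called, 3862 higher and 2325 lower in LysoMac. Of all genes tested, 1600 did not overlap between the arrays of both sides (0.0162% by chance). After shifts to a common median the split was 2473 higher and 3199 lower. Camera called the lists at adjusted p between 2.52e-14 (lysosome) and 0.000127 (antimicrobial factors). With an estimated correlation the calls held at adjusted p = 0.00236 (interferon-stimulated, cDC1 and macrophage lists), 0.00763 (GTPases and MHC class II), 0.0125 (chemokine receptors) and 0.0176 (lysosome and antimicrobial factors). They were lost for cell cycle (adjusted p = 0.0532 with an estimated correlation) and for dissociation genes (adjusted p = 0.15 with an estimated correlation). Against CD11b+ and DN cDC alone, inside 1 array set, 5189 of 16549 genes were called. There the lysosome list had 25 of 27 members higher and 1 lower, and MHC class II had 9 of 11 lower and 1 higher.

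TIM-4+ and TIM-4- LysoMac (3 arrays each, 1 array set) differed in few genes. Besides Timd4 itself, the phosphatidylserine receptor used in the sort (5.12 ± 0.32), TIM-4+ cells had higher Cybrd1, a ferric reductase (1.86 ± 0.15), and the efflux transporter Abcc3 (1.36 ± 0.17). They also had higher Madcam1, the vascular ligand of the integrin α4β7 (1.19 ± 0.15), Igf1, a growth factor (1.13 ± 0.13), and the integrin chain Itga6 (1.06 ± 0.16). Lower in TIM-4+ cells were the surface protein Plet1 (-3.13 ± 0.33), the ectoenzyme Bst1 (-2.25 ± 0.26), the IL-1 decoy receptor Il1r2 (-1.99 ± 0.30) and the cytokine Il1b (-1.72 ± 0.28). Of the other sort markers Itgam was lower (-1.39 ± 0.21). Cd4 (0.71 ± 0.18, adjusted p = 0.103), Itgax (-0.35 ± 0.16, adjusted p = 0.791), Sirpa (0.02 ± 0.28) and Bst2 (0.10 ± 0.19) were not called.

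MHC class II presentation genes were lower in TIM-4+ LysoMac for 5 of 11 members and higher for 0 (7 and 0 adjusted over the list alone). The largest differences were those of H2-Aa (-2.24 ± 0.22), H2-Eb1 (-1.97 ± 0.15), the invariant chain Cd74 (-1.95 ± 0.23) and H2-Ab1 (-1.94 ± 0.19). The list was called at adjusted p = 3.91e-18, and at adjusted p = 0.00718 with an estimated correlation. Cholesterol synthesis genes had 1 of 14 members lower, Fdps (-0.54 ± 0.12), and 7 lower over the list alone, with a median of -0.43. This list's call at adjusted p = 1.91e-11 was lost at adjusted p = 0.0622 with an estimated correlation. The cDC2 signature had 1 of 21 members lower (3 over the list alone, median -0.20, adjusted p = 6.4e-05, and adjusted p = 0.105 with an estimated correlation). Glycolysis genes had a median of -0.17 with 0 of 13 members called and 1 lower over the list alone (adjusted p = 0.0095, and adjusted p = 0.603 with an estimated correlation). The macrophage signature had 0 of 26 members called. Among markers of other cells, Madcam1 was called of 10 stromal and endothelial genes (list adjusted p = 0.0104, and adjusted p = 0.322 with an estimated correlation). Plasmacytoid DC markers had 1 of 8 lower (2 over the list alone, median -0.20, list adjusted p = 0.0418, and adjusted p = 0.199 with an estimated correlation). T cell markers had 0 of 8 called (median -0.18, list adjusted p = 0.0563, and 0.0381 after cyclic loess).

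In total 73 of 16549 genes were called, 32 higher and 41 lower in TIM-4+ cells, and 34 of them by at least 2-fold. Of all genes tested, 1780 did not overlap between the arrays (10% by chance). The count fell to 43 without TIM-4- replicate 1 and to 44 without TIM-4- replicate 3, and 27 were called when the 6 arrays were fitted alone, where H2-Aa, H2-Ab1, Cd74, Il1b, Madcam1, Abcc3 and Fdps lost their calls. Fdps also lost its call with any 1 array left out. With 79 of 100 simulated 2-fold changes recovered, smaller differences could not be ruled out.

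Untreated CD8α+ cDC (3 arrays) differed from untreated CD11b+ cDC (5 arrays) in the genes that separate both lineages of conventional dendritic cells. Higher in CD8α+ cDC were the receptor Gpr33 (5.71 ± 0.16), P2ry14, a receptor for UDP sugars (4.54 ± 0.30), the lectin Clec12a (4.44 ± 0.19), the chemokine receptor Cxcr3 (4.26 ± 0.20), Tlr12, a sensor of profilin (4.10 ± 0.19), and the adhesion molecule Cadm1 (4.01 ± 0.17). Lower in CD8α+ cDC were Ifitm1, an interferon-induced membrane protein (-5.74 ± 0.22), Il1r2 (-5.74 ± 0.27), the receptor Csf1r (-5.18 ± 0.29), Cybb, the catalytic chain of the phagocyte oxidase (-4.87 ± 0.33), and the transcription factor Spib (-4.82 ± 0.23). Of the sort markers, Itgam (-3.21 ± 0.19), Timd4 (-3.22 ± 0.29) and Cd4 (-0.82 ± 0.16) were lower, and Itgax was -0.26 ± 0.14 (adjusted p = 0.135). Cd8a had no accepted row in the untreated CD11b+ arrays.

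The cDC1 signature had 13 of 15 members higher in CD8α+ cDC and 2 lower (the same over the list alone). The exceptions were Fkbp1b (-1.63 ± 0.19) and the transcription factor Batf3 (-0.51 ± 0.14), whose call was lost after shifts to a common median and after cyclic loess. The cDC2 signature had 13 of 17 lower and 3 higher (the same over the list alone), with the transcription factor Zeb2 at -3.53 ± 0.13. Antimicrobial factors were lower for 10 of 11 and higher for 1 (the same over the list alone). Pglyrp1 was at -3.03 ± 0.23 and the pore protein Mpeg1 at 3.37 ± 0.15. MHC class I presentation genes had 4 of 12 higher and 2 lower (the same over the list alone), with 7 and 1 after shifts to a common median and 9 and 1 after cyclic loess. The peptide transporter chains Tap2 (1.13 ± 0.09) and Tap1 (0.99 ± 0.11) were higher and Psmb10 lower (-1.16 ± 0.22). Maturation and co-stimulation genes were lower for 10 of 14 and higher for 1 (the same over the list alone), among them Socs2 (-2.75 ± 0.27) and, in the other direction, Cd86 (1.38 ± 0.20). Cytokine genes were lower for 8 of 13 and higher for 1 (the same over the list alone, list adjusted p = 0.064, and 0.0165 after cyclic loess), but lower for 5 and higher for 2 with a common median, and 5 and 1 with cyclic loess. Il1rn, the IL-1 receptor antagonist, was at -3.92 ± 0.17 and Il6 at -3.43 ± 0.30. Genes of the marker lists of other cells were lower in CD8α+ cDC too. The plasmacytoid DC list averaged 5.30 in untreated CD8α+ cDC, against 6.48 in CD11b+ cDC, 6.91 in DN cDC and 6.77 and 6.47 in TIM-4- and TIM-4+ LysoMac. Its level thus does not single out admixed cells in CD11b+ cDC. The lower genes were as follows. These were 7 of 7 plasmacytoid DC markers (7 over the list alone, 4 with a common median and 4 with cyclic loess), such as Lair1 (-3.23 ± 0.20), and 5 of 7 T cell markers (5 over the list alone, list adjusted p = 0.0783, and 0.0331 after cyclic loess), such as Thy1 (-3.32 ± 0.34). Of the other marker lists, NK cell and ILC markers had 6 of 8 lower and 2 higher, neutrophil markers 5 of 8 lower, epithelial markers 5 of 13 lower, plasma cell markers 4 of 7 lower, mast cell and basophil markers 4 of 8 lower and B cell markers 3 of 6 lower. With a common median these were 5 lower and 2 higher, and 2, 3, 0, 0 and 1 lower, and camera called none of them, the closest at adjusted p = 0.114.

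Camera called the cDC1 list at adjusted p = 4.56e-20, and at adjusted p = 6.78e-05 with an estimated correlation. The call of the cDC2 list (adjusted p = 0.00194) was lost at adjusted p = 0.174 with an estimated correlation. Those of MHC class I (0.00266), antimicrobial factors (0.00411) and plasmacytoid DC markers (0.0182) were lost at adjusted p = 0.117 each with an estimated correlation. Maturation (0.0182) was lost at adjusted p = 0.356 with an estimated correlation. Across the genes 6895 of 14519 were called, 1256 higher and 5639 lower in CD8α+ cDC. Called or not, 6372 genes did not overlap between the arrays (3.57% by chance). The groups lay in different array sets, and the median of all genes was -0.19. The split was 3392 higher and 2112 lower after shifts to a common median (median of all genes 0.07) and 2638 higher and 2675 lower after cyclic loess, which left 3931 genes called in the same direction under cyclic loess.

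DN cDC (3 arrays) differed from CD11b+ cDC (5 arrays) in fewer genes, led by matrix and vascular genes. Higher in DN cDC were Sparc, a protein of the extracellular matrix (4.97 ± 0.47), Igfbp7 (4.95 ± 0.45), the endothelial sialomucin Emcn (3.88 ± 0.23), the fatty acid carrier Fabp4 (3.66 ± 0.41) and the matrix proteoglycan Bgn (3.32 ± 0.09). Lower in DN cDC were the cystine transporter Slc7a11 (-2.40 ± 0.17), Gp2, the bacterial uptake receptor of M cells (-2.29 ± 0.20), the chemokine Ccl17 (-2.23 ± 0.29) and Acod1 (-2.21 ± 0.41). Among the sort markers Itgam (-1.56 ± 0.19) and Timd4 (-1.31 ± 0.29) were lower, and Itgax (-0.29 ± 0.14), Sirpa (-0.37 ± 0.25), Bst2 (-0.13 ± 0.17) and Cd4 (0.37 ± 0.16) were not called, the closest at adjusted p = 0.225.

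Stromal and endothelial markers, which belong to other cell types, were higher in DN cDC for 8 of 10 members and lower for 0 (9 and 0 adjusted over the list alone). They included Cdh5, the cadherin of endothelium (2.43 ± 0.25), Dcn (1.72 ± 0.11) and Pdgfra (0.85 ± 0.10). Epithelial markers had 2 of 15 higher and 1 lower (4 and 2 over the list alone), with Fabp1 at 3.31 ± 0.88 and Vil1 at 1.12 ± 0.30, both without a call when arrays were weighted. Plasmacytoid DC markers had 2 of 8 higher and 0 lower (3 and 0 over the list alone, median 0.34), and T cell markers 1 of 8 higher and 0 lower (2 and 0 over the list alone, median 0.35). B cell markers had 0 of 7 called (median -0.33, list adjusted p = 0.0553, and 0.0252 after cyclic loess). Maturation and co-stimulation genes were lower for 10 of 22 and higher for 1 (13 and 1 over the list alone), and 12 were lower with a common median and 8 with cyclic loess. Ccr7 (-1.73 ± 0.30), the co-stimulatory ligand Tnfsf9 (-1.44 ± 0.30) and Socs2 (-1.19 ± 0.27) were lower and Slamf1 was higher (1.11 ± 0.29). The call of Slamf1 was lost after shifts to a common median, and those of Tnfsf9, Socs2 and Timd4 without DN replicate 2. Chemokines had 4 of 21 lower and 0 higher (the same over the list alone, list adjusted p = 0.207), among them Ccl22 (-2.04 ± 0.29). In the cDC2 signature 4 of 21 were lower and 0 higher (6 and 1 over the list alone), such as the lectins Mgl2 (-2.13 ± 0.25) and Cd209a (-1.93 ± 0.29). The median of this list was 0.21, its mean was -0.14, and camera did not call it (adjusted p = 0.935). MHC class II presentation had 0 of 11 called.

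The stromal and endothelial list was called at adjusted p = 6.65e-16, and at adjusted p = 0.00413 with an estimated correlation. The calls of maturation (adjusted p = 2.17e-07) and epithelial markers (0.0116) were lost at adjusted p = 0.144 and adjusted p = 0.53 with an estimated correlation. Those of plasmacytoid DC (0.00223) and T cell markers (0.00238) were lost at adjusted p = 0.0738 and adjusted p = 0.144 with an estimated correlation. Glycolysis (9.91e-05, median -0.41) and cell cycle genes (0.00042, median -0.36) were lost at adjusted p = 0.483 each with an estimated correlation. Cholesterol synthesis (0.000896, median -0.31) was lost at adjusted p = 0.342 with an estimated correlation. Altogether 704 of 16549 genes were called, 423 higher and 281 lower. Of all genes tested, 1598 did not overlap between the arrays (3.57% by chance). The split was 328 higher and 528 lower after shifts to a common median. The count was 464 without DN replicate 2, 326 with the 8 arrays fitted alone, and 4081 (1494 higher, 2587 lower) with CD11b+ replicates 4 and 5 as the only CD11b+ arrays.

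Against CD8α+ cDC (3 arrays), DN cDC (3 arrays) were compared across array sets. Ifitm1 (5.45 ± 0.24), Il1r2 (5.36 ± 0.30) and Cybb (4.70 ± 0.37) were higher in DN cDC, and Gpr33 (-5.71 ± 0.18), Apol7c (-4.68 ± 0.62) and Irf8, the transcription factor of the cDC1 lineage (-3.95 ± 0.21), were lower. Sparc (5.52 ± 0.52) and Cdh17, a cadherin of gut epithelium (4.68 ± 0.33), were higher as well. Sort markers were higher for Timd4 (1.91 ± 0.32), Itgam (1.65 ± 0.21) and Cd4 (1.19 ± 0.18), with Itgax at -0.04 ± 0.16 (adjusted p = 0.867).

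The cDC1 signature was lower in DN cDC for 12 of 15 members and higher for 1 (13 and 1 over the list alone), with Tlr12 at -3.55 ± 0.22. The cDC2 signature was higher for 12 of 17 and lower for 3 (12 and 4 over the list alone). With a common median 10 were higher and 5 lower. Csf1r was at 4.47 ± 0.32 and Rbpj at -1.31 ± 0.14. The macrophage signature had 12 of 23 higher and 1 lower (14 and 1 over the list alone), with Cx3cr1 at 2.02 ± 0.25. Its counts were 7 and 3 after shifts to a common median and 8 and 2 after cyclic loess. MHC class I genes had 5 of 12 lower and 0 higher (7 and 2 over the list alone, 9 lower with a common median and 8 with cyclic loess), with Tap1 at -1.18 ± 0.13. Genes of the marker lists of other cells were higher in DN cDC. Of 8 stromal and endothelial markers 7 were higher and 1 was lower (the same over the list alone), such as Cdh5 (2.76 ± 0.28). Higher as well were 10 of 13 epithelial markers (11 over the list alone, 6 with a common median, 7 with cyclic loess, list adjusted p = 0.0576, and 0.00594 after cyclic loess), 5 of 7 T cell markers (5 over the list alone), such as Cd3g (3.33 ± 0.61), and 6 of 7 plasmacytoid DC markers (6 over the list alone), such as Lair1 (3.29 ± 0.22). NK cell and ILC markers had 6 of 8 higher and 2 lower (list adjusted p = 0.26), and neutrophil markers 4 of 8 higher (2 with a common median, list adjusted p = 0.15).

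The cDC1 call held at adjusted p = 5.3e-20, and at adjusted p = 6.9e-05 with an estimated correlation. MHC class I (adjusted p = 0.00116) and T cell markers (0.0129) were lost at adjusted p = 0.0811 each with an estimated correlation. The cDC2 (0.0106) and macrophage lists (0.0258) were lost at adjusted p = 0.266 each with an estimated correlation. Plasmacytoid DC (0.00123) and stromal markers (0.00588) were lost at adjusted p = 0.05 and adjusted p = 0.173 with an estimated correlation. Of 14519 genes 6166 were called, 4791 higher and 1375 lower in DN cDC, and 8457 of all genes tested did not overlap between the arrays (10% by chance). The median of all genes was 0.16, and -0.16 after shifts to a common median, with which the split turned to 1786 higher and 4843 lower. Cyclic loess gave 2685 higher and 2640 lower, with 4057 genes called in the same direction.

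Placed on the axis from CD8α+ cDC (0) to CD11b+ cDC (1) over the 6895 genes that differed between them, DN cDC lay at 0.953 ± 0.016 (mean ± SD, 3 arrays). CD11b+ arrays measured in the same way lay at 0.981 ± 0.023 (5 arrays) and CD8α+ arrays at 0.016 ± 0.043 (3 arrays). DN and CD11b+ cDC did not differ in an exact two-sided permutation test (p = 0.107, smallest possible 0.0179). For DN against CD8α+ cDC the exact two-sided permutation p was 0.1, which is the smallest that 3 against 3 arrays allow. CD11b+ and DN arrays shared an array set, and CD8α+ arrays did not.

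**Figure D2:**
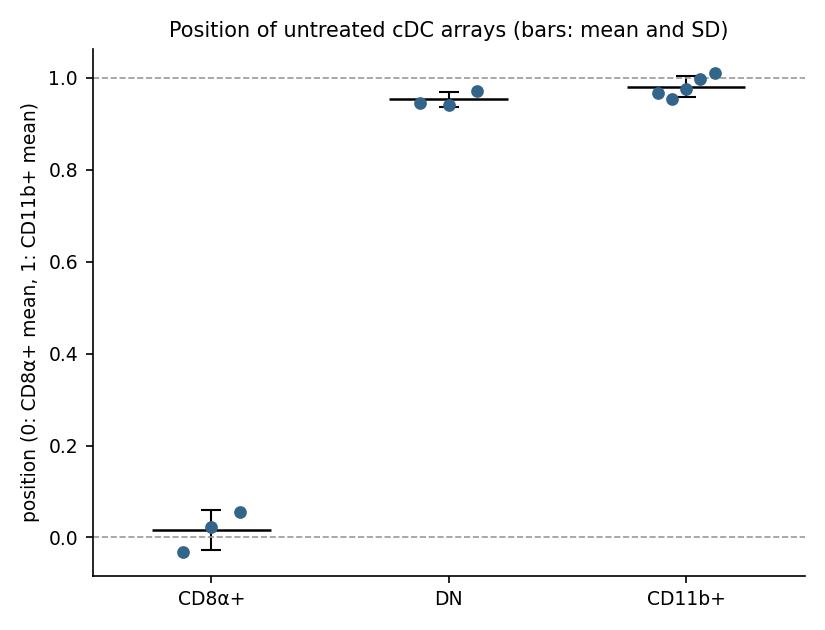
Position (y axis, no unit) of each untreated CD8α+, DN and CD11b+ cDC array (x axis) between the CD8α+ mean at 0 and the CD11b+ mean at 1, one point per array, with bars for the mean and SD of the group. The DN mean was 0.953 and the CD11b+ mean was 0.981.

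In CD11b+ cDC, R848 (3 arrays against 5 untreated) was followed by higher expression of interferon-stimulated and maturation genes. The largest rises included Il15, a cytokine that sustains NK and T cells (4.56 ± 0.28), the GTPase Gbp5 (4.23 ± 0.19), Il2ra, a chain of the IL-2 receptor (3.92 ± 0.23), Irf7 (3.80 ± 0.15), Il7r (3.72 ± 0.19) and the lipid-presenting molecule Cd1d1 (3.59 ± 0.20). The largest falls included the glutaminyl cyclase Qpct (-4.39 ± 0.17), Hpgd, which degrades prostaglandins (-4.02 ± 0.25), Anxa1 (-3.76 ± 0.18), Pglyrp1 (-3.49 ± 0.23) and Alox5ap (-3.44 ± 0.25). Among the sort markers Itgam (-2.88 ± 0.19), Itgax (-1.21 ± 0.14), Timd4 (-0.83 ± 0.29) and Sirpa (-0.76 ± 0.25) fell, Bst2 rose (1.06 ± 0.17), and Cd4 was -0.10 ± 0.16 (adjusted p = 0.636). The call of Timd4 was lost after cyclic loess and that of Sirpa without R848 replicate 1.

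Of 22 interferon-stimulated genes 20 rose and 0 fell (the same over the list alone), with the antiviral GTPase Mx1 (3.44 ± 0.17), the nucleic acid sensor Zbp1 (3.05 ± 0.16) and Xaf1 (2.25 ± 0.12). Of 8 interferon-gamma-inducible GTPases 7 rose and 0 fell (the same over the list alone), Gbp4 by 2.90 ± 0.22. Maturation and co-stimulation genes rose for 15 of 22 and fell for 3 (the same over the list alone). The co-stimulatory receptors Tnfrsf4 (3.45 ± 0.35) and Tnfrsf9 (3.44 ± 0.25), Socs2 (2.74 ± 0.27) and the actin bundler Fscn1 (2.18 ± 0.21) rose, and Tnfsf9 (-0.97 ± 0.30) and Cd86 (-0.63 ± 0.20) fell, with calls that were lost when the 8 arrays were fitted alone. MHC class I genes rose for 7 of 13 and fell for 0 (the same over the list alone), with Tapbpl (1.71 ± 0.16), H2-Q4 (1.39 ± 0.15) and Tap1 (1.15 ± 0.11). Chemokines rose for 9 of 21 and fell for 2 (9 and 4 over the list alone, list adjusted p = 0.0542). The CXCR3 ligands Cxcl10 (2.75 ± 0.32) and Cxcl9 (2.40 ± 0.35) and Ccl5 (1.96 ± 0.41) were among the rises. The cDC2 signature fell for 11 of 21 and rose for 4 (12 and 5 over the list alone), with Cd209a at -3.38 ± 0.29. Glycolysis genes fell for 10 of 13 and rose for 1 (the same over the list alone), with the glucose transporter Slc2a1 (-1.71 ± 0.23) and Ldha (-1.54 ± 0.09) against Pfkfb3 (1.55 ± 0.11). Cholesterol synthesis genes rose for 5 of 14 and fell for 1 (the same over the list alone, 8 and 1 with cyclic loess), Idi1 by 1.63 ± 0.18.

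Markers of B cells rose beside these lists, with 7 of 7 higher (7 over the list alone), such as Ms4a1 (2.74 ± 0.28) and Cd79b (2.14 ± 0.37). Of 7 plasma cell markers 4 rose (4 over the list alone, 1 lower there, list adjusted p = 0.0759), such as Jchain (2.88 ± 0.65). T cell markers fell for 6 of 8 and rose for 1 (the same over the list alone, list adjusted p = 0.0731). Dissociation and immediate early genes fell for 8 of 15 and rose for 1 (9 and 1 over the list alone), with Nr4a1 at -3.12 ± 0.26. Glucocorticoid-induced genes fell for 7 of 10 and rose for 0 (7 and 1 over the list alone, 5 and 1 with cyclic loess), with the metallothionein Mt1 at -1.55 ± 0.22. Epithelial markers fell for 5 of 15 and rose for 0 (the same over the list alone), with Epcam at -2.22 ± 0.19.

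The interferon lists were called at adjusted p = 4.17e-18 and 8.78e-07, and at adjusted p = 0.000391 and adjusted p = 0.00415 with an estimated correlation. Maturation (adjusted p = 1.13e-05) and B cell markers (8.57e-05) were lost at adjusted p = 0.202 each with an estimated correlation. MHC class I (0.000245), cDC2 (0.00548) and glycolysis genes (0.00381) were lost at adjusted p = 0.162, adjusted p = 0.222 and adjusted p = 0.426 with an estimated correlation. Glucocorticoid-induced genes (0.0143) were lost at adjusted p = 0.316 with an estimated correlation. Epithelial markers (0.0335), cholesterol synthesis and dissociation genes (0.0412 each) were lost at adjusted p = 0.432 each with an estimated correlation, the dissociation call also after cyclic loess at adjusted p = 0.095. Of 16549 genes 6779 were called, 2920 higher and 3859 lower after R848, and 6286 of all genes tested did not overlap between the arrays (3.57% by chance). Treated and untreated arrays lay in different array sets. The split was 4028 higher and 3036 lower after shifts to a common median, and 3473 and 3186 after cyclic loess, with 5669 genes called in the same direction.

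In CD8α+ cDC, R848 (5 arrays against 3 untreated) was followed by rises of Spib, a transcription factor (6.56 ± 0.23), Socs2, a suppressor of cytokine signals (5.44 ± 0.27), the lipid carrier Apod (5.20 ± 0.13), Tnfrsf4 (5.14 ± 0.35) and Nudt17 (4.93 ± 0.35). Spib was also far lower in untreated CD8α+ than in untreated CD11b+ cDC, and the untreated CD8α+ arrays form an array set of their own. Its low untreated level and that set cannot be told apart. Falls were found for Qpct (-5.04 ± 0.17), the endosomal exchanger Slc9a9 (-4.73 ± 0.21), Rab7b, a GTPase of endosomes (-4.47 ± 0.26), Cxcr3 (-4.33 ± 0.20) and the scaffold protein Iqgap2 (-4.29 ± 0.14). Of the sort markers Itgax fell (-2.82 ± 0.14) and Cd8a rose (0.47 ± 0.16, a call lost after shifts to a common median and after cyclic loess), while Cd4 (0.32 ± 0.16, adjusted p = 0.0883), Itgam (0.35 ± 0.19, adjusted p = 0.124) and Timd4 (0.58 ± 0.29, adjusted p = 0.0897) were not called. Sirpa and Bst2 had no accepted row in the untreated CD8α+ arrays.

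Interferon-stimulated genes rose for 18 of 20 and fell for 0 (the same over the list alone), with Oasl2 (4.22 ± 0.12), Mx1 (3.92 ± 0.17) and Irf7 (3.65 ± 0.15). Of 7 interferon-gamma-inducible GTPases 6 rose and 0 fell (the same over the list alone), Gbp5 by 4.66 ± 0.19. Maturation and co-stimulation genes rose for 13 of 16 and fell for 1 (14 and 1 over the list alone), with the regulatory ligand Cd200 (3.30 ± 0.14) and Tnfrsf9 (3.21 ± 0.25) against Cd86 (-2.10 ± 0.20). The cDC1 signature fell for 16 of 18 and rose for 1 (the same over the list alone), with Itgae at -4.10 ± 0.27. MHC class II genes fell for 7 of 10 and rose for 2 (the same over the list alone), with Ciita (-2.78 ± 0.12) and H2-Ob (-2.52 ± 0.17) against H2-Eb2 (1.65 ± 0.19). MHC class I genes rose for 10 of 13 and fell for 0 (the same over the list alone), with H2-Q4 (1.71 ± 0.15) and the proteasome activator Psme2 (1.53 ± 0.22). Cholesterol synthesis genes rose for 8 of 11 and fell for 0 (9 and 0 over the list alone), with Idi1 (3.51 ± 0.18) and Fdft1 (2.16 ± 0.16). Glycolysis genes fell for 7 of 15 and rose for 3 (the same over the list alone, 8 and 1 with a common median), with Ldha (-1.89 ± 0.09) against Pfkfb3 (3.55 ± 0.11). Among chemokines and trafficking genes Ccl5 (3.84 ± 0.41), the CCR7 ligand Ccl19 (3.17 ± 0.17), the egress receptor S1pr1 (3.93 ± 0.23) and Ccr7 (2.84 ± 0.30) rose and Ccl17 fell (-2.85 ± 0.29). Chemokines rose for 10 of 19 and fell for 4 (11 and 4 over the list alone, list adjusted p = 0.478). Chemokine receptor and trafficking genes rose for 10 of 17 and fell for 5 (the same over the list alone, list adjusted p = 0.538), with a median of 0.54 and a mean of -0.26.

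Markers of B cells rose for 7 of 10 (7 over the list alone, median 1.11, list adjusted p = 0.197, and 0.0256 after cyclic loess), such as Cd79a (3.85 ± 0.35). T cell markers rose for 9 of 10 (9 over the list alone, list adjusted p = 0.0635, and 0.0369 after cyclic loess), but for 5 with a common median and 4 with cyclic loess, such as Cd3g (1.93 ± 0.54). NK cell and ILC markers rose for 7 of 10 and fell for 0 (the same over the list alone, 5 and 0 with a common median, list adjusted p = 0.328). Mast cell and basophil markers rose for 6 of 9 and fell for 1, but 1 and 1 with a common median (list adjusted p = 0.538). Dissociation and immediate early genes fell for 8 of 16 and rose for 1 (the same over the list alone), with Nr4a1 at -3.68 ± 0.26. Cell cycle genes fell for 8 of 26 and rose for 0 (5 and 0 over the list alone, 12 and 0 with a common median, 6 and 0 with cyclic loess), with Mcm3 at -1.27 ± 0.28.

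The cDC1 call (adjusted p = 1.08e-13) held at adjusted p = 0.0162 with an estimated correlation. The interferon calls (adjusted p = 9.89e-08 and 0.000915) were lost at adjusted p = 0.0556 each with an estimated correlation. Maturation (6.13e-05), glycolysis (0.00591) and cholesterol synthesis (0.0437) were lost at adjusted p = 0.305 each with an estimated correlation. Dissociation (2.97e-05) and cell cycle genes (0.000425) were lost at adjusted p = 0.0698 and adjusted p = 0.51 with an estimated correlation. After cyclic loess the calls of cell cycle and glycolysis genes were lost too (adjusted p = 0.0506 and 0.0516). MHC class II (0.000437) and MHC class I genes (0.0213) were lost at adjusted p = 0.155 and adjusted p = 0.355 with an estimated correlation. Of 16697 genes 9477 were called, 7005 higher and 2472 lower, and 9543 of all genes tested did not overlap between the arrays (3.57% by chance). The groups lay in different array sets with a median of all genes of 0.18. The split was 3511 higher and 3493 lower after shifts to a common median and 3654 and 3521 after cyclic loess, with 6083 genes called in the same direction.

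Both responses used the same R848 array set, while their untreated arrays lay in different sets, and an effect of the R848 set enters both. Of 14519 genes tested in both, 5940 were called in CD11b+ and 8218 in CD8α+ cDC, and 3299 were called in the same direction (1953 higher and 1346 lower in both). Independent lists would share 1561, a value that leaves out the shared set and so does not measure chance here. In opposite directions 540 were called. At 2-fold or more, 302 rose in both, 304 fell in both and 16 went in opposite directions. Across genes, which are not independent replicates, the log2 responses correlated at r = 0.645 (rho = 0.563), and at r = 0.664 over the 10319 genes called in at least 1 response.

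**Figure D3:**
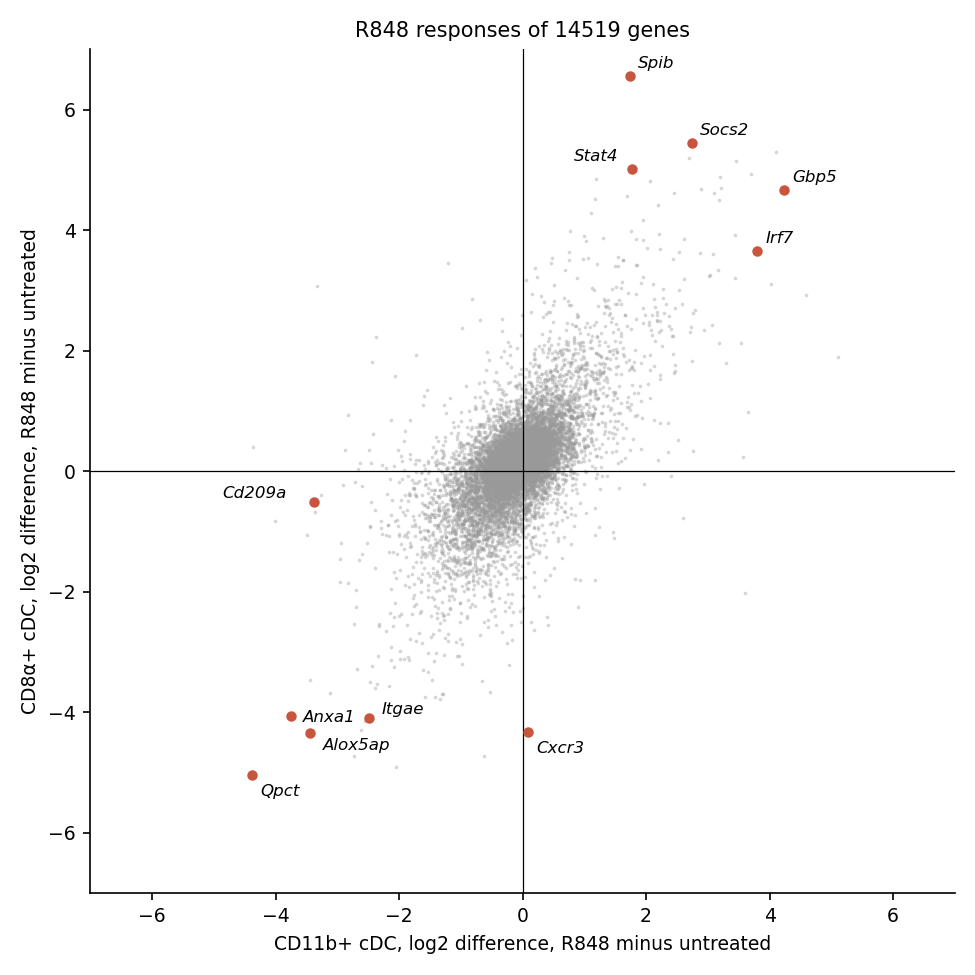
Log2 response to R848 of CD8α+ cDC (y axis) against that of CD11b+ cDC (x axis) for 14519 genes, one point per gene, with named genes in red. Irf7 lay at 3.80 and 3.65 in CD11b+ and CD8α+ cDC, Qpct at -4.39 and -5.04, and Cxcr3 at -4.33 in CD8α+ cDC.

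The responses of CD8α+ and CD11b+ cDC were also compared by a test of the difference itself. The untreated arrays of both lay in different array sets, so a difference between these sets enters the values and could not be separated from the response. Compared with CD11b+ cDC, the response of CD8α+ cDC was higher for Gzma, a granule protease of cytotoxic lymphocytes (6.41 ± 0.94), Spib (4.82 ± 0.33), the metallothionein Mt2 (4.67 ± 0.61), the surface protein Cd7 (4.25 ± 0.60), Thy1 (3.76 ± 0.48) and Lgmn (3.67 ± 0.31). It was lower for Cxcr3 (-4.42 ± 0.28), the integrin chain Itga8 (-2.99 ± 0.18), Tlr12 (-2.97 ± 0.27), Cadm1 (-2.84 ± 0.24), P2ry14 (-2.81 ± 0.42) and Igf2r (-2.73 ± 0.18). Of the sort markers Itgam (3.23 ± 0.27) and Timd4 (1.41 ± 0.41) had the higher response in CD8α+ cDC and Itgax the lower (-1.61 ± 0.20), with Cd4 at 0.42 ± 0.22 (adjusted p = 0.149). The call of Timd4 was lost after shifts to a common median.

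The cDC1 signature responded lower in CD8α+ than in CD11b+ cDC for 12 of 15 members and higher for 2 (the same over the list alone), with Irf8 at -2.08 ± 0.27. The mean of this list went from 9.21 to 7.201 in CD8α+ cDC and from 6.642 to 6.196 in CD11b+ cDC. Its genes thus started higher in CD8α+ cDC and had more room to fall there. The cDC2 signature responded higher for 12 of 17 and lower for 2 (13 and 2 over the list alone, 8 and 2 with a common median, list adjusted p = 0.061, and 0.00389 after cyclic loess), with Cd209a at 2.87 ± 0.41. Here the list mean fell from 7.555 to 6.416 in CD11b+ cDC and stayed at 5.707 in CD8α+ cDC. The difference thus reflected a fall in CD11b+ cDC and not a rise in CD8α+ cDC. Maturation and co-stimulation genes responded higher for 10 of 14 and lower for 1 (the same over the list alone). They included Tnfsf9 (3.35 ± 0.43), Socs2 (2.70 ± 0.39), and the PD-1 ligands Pdcd1lg2 (2.60 ± 0.24) and Cd274 (2.18 ± 0.14), against Cd86 (-1.47 ± 0.28). MHC class II genes responded lower for 4 of 10 and higher for 1 (5 and 1 over the list alone), with Ciita at -1.77 ± 0.16. Interferon-stimulated genes responded higher for 9 of 17 and lower for 1 (the same over the list alone, 6 and 1 with a common median, list adjusted p = 0.247), with Oas1a at 1.27 ± 0.29 and Trim30a at -1.06 ± 0.17. Cxcl9 (-2.48 ± 0.49) and Cxcl10 (-2.42 ± 0.45) responded lower in CD8α+ cDC, among 4 lower and 5 higher of 19 chemokines (the same over the list alone). The chemokine counts were 5 lower and 2 higher with a common median and 5 and 3 with cyclic loess. T cell markers, which belong to other cells, responded higher for 5 of 7 and lower for 0 (the same over the list alone), with Cd3g at 3.65 ± 0.77. NK cell and ILC markers responded higher for 5 of 8 and lower for 2 (3 and 2 with a common median, list adjusted p = 0.209), and neutrophil markers higher for 6 of 8 (3 with a common median, list adjusted p = 0.139).

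Camera called the cDC1 list at adjusted p = 1.31e-15, and at adjusted p = 5.63e-05 with an estimated correlation. The calls of MHC class II (adjusted p = 0.00718), maturation and T cell markers (0.0164 each) were lost at adjusted p = 0.327, adjusted p = 0.452 and adjusted p = 0.327 with an estimated correlation. Of 14519 genes 4801 were called, 3941 with a higher and 860 with a lower response in CD8α+ cDC. For 86 of all genes tested, R848 CD8α+ and untreated CD11b+ arrays together did not overlap with untreated CD8α+ and R848 CD11b+ arrays (0.025% by chance). That count does not measure differing responses, since a gene with unequal untreated levels can fail it. The median of all genes was 0.21, and after shifts to a common median 3118 were called, 1368 higher and 1750 lower. Cyclic loess gave 1643 higher and 1724 lower with 2503 genes called in the same direction.

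**Figure D4:**
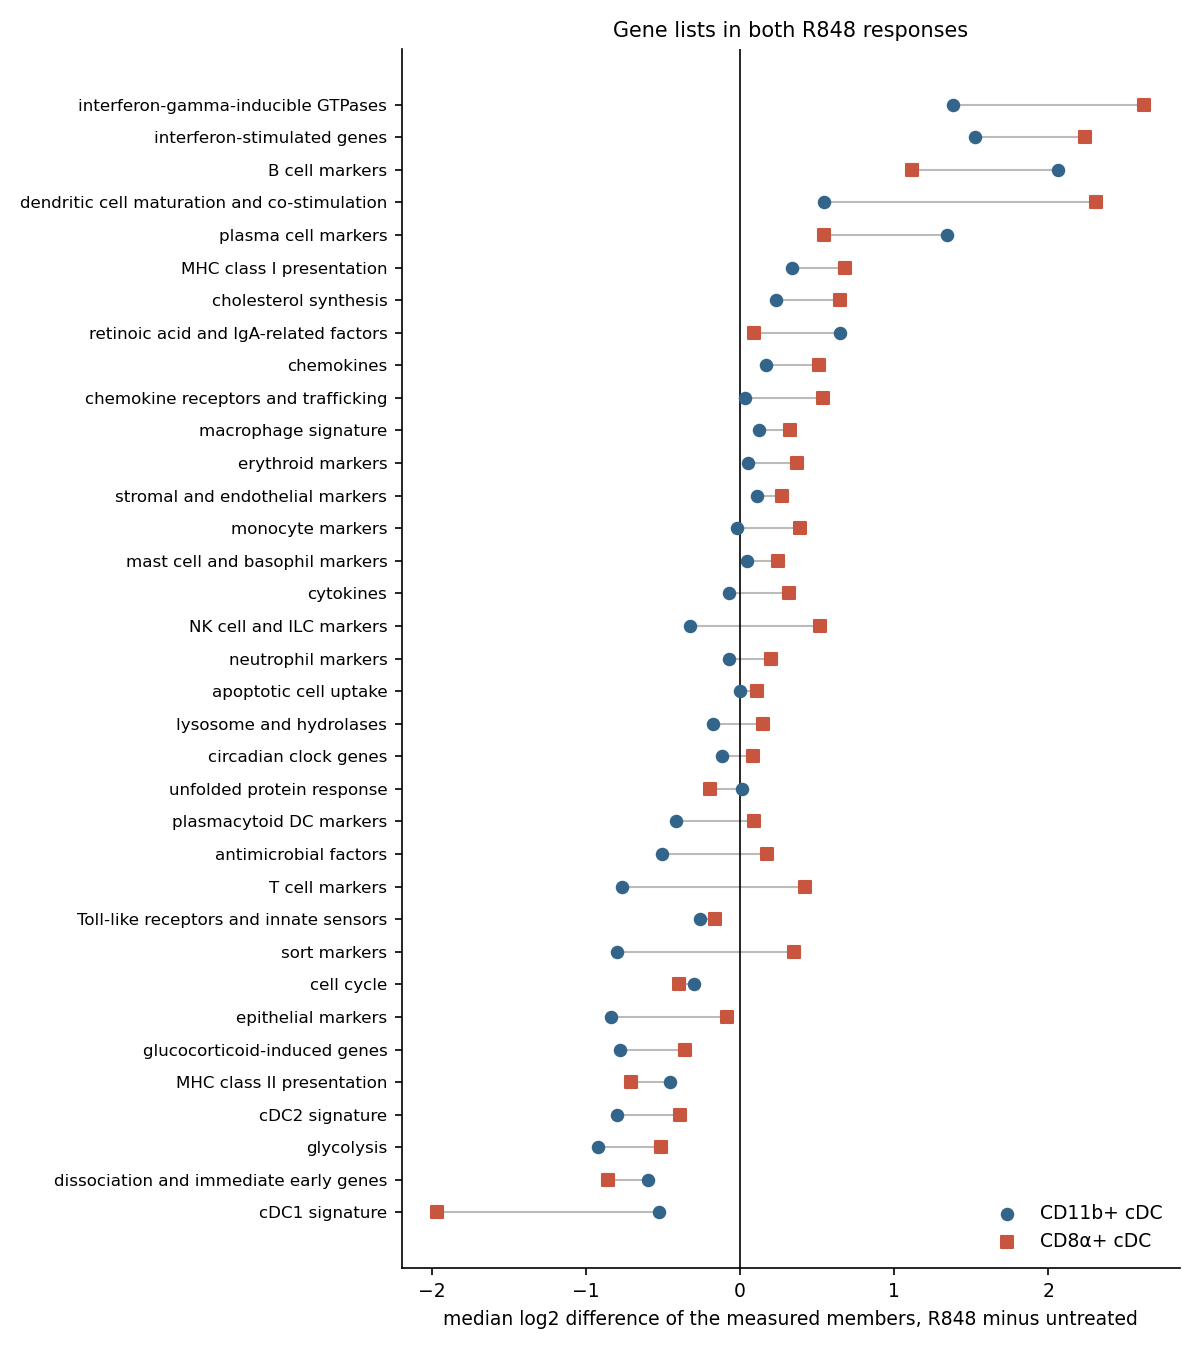
Median log2 response to R848 (x axis) of the measured members of each gene list (y axis) in CD11b+ cDC (blue circles) and CD8α+ cDC (red squares), with a line joining both. The interferon-stimulated genes lay at 1.52 and 2.24, and the cDC1 signature at -1.96 in CD8α+ cDC.

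Compared inside 1 array set, after R848, CD8α+ cDC (5 arrays) and CD11b+ cDC (3 arrays) differed by lineage genes. This comparison was added after seeing the data. Higher in CD8α+ cDC were Clec9a, a receptor for dead cells (5.33 ± 0.21), Clec12a (5.20 ± 0.19), the chemokine receptor Xcr1 (4.72 ± 0.12), Gpr33 (3.95 ± 0.16), Ccl19 (3.69 ± 0.17) and the sort marker Cd8a (3.59 ± 0.16). Lower in CD8α+ cDC were Plet1 (-5.19 ± 0.29), Tarm1 (-4.98 ± 0.19), the chemokines Ccl8 (-3.98 ± 0.18) and Ccl3 (-3.74 ± 0.47), the chemokine receptor Ccr9 (-3.91 ± 0.14) and Il1b (-3.86 ± 0.25). The sort markers Sirpa (-3.34 ± 0.25), Itgax (-1.86 ± 0.14) and Timd4 (-1.80 ± 0.29) were lower. Itgam (0.01 ± 0.19), Cd4 (-0.40 ± 0.16, adjusted p = 0.117) and Bst2 (0.14 ± 0.17) were not called.

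The cDC1 signature was higher in CD8α+ cDC for 16 of 26 members and lower for 0 (17 and 3 over the list alone), with the scavenger receptor Cd36 at 2.14 ± 0.17. The cDC2 signature was lower for 15 of 27 and higher for 1 (17 and 2 over the list alone), with Il1r2 (-3.06 ± 0.27), Zeb2 (-2.72 ± 0.13) and Csf1r (-2.61 ± 0.29). MHC class I genes were higher for 9 of 15 and lower for 0 (11 and 0 over the list alone), with Tap2 at 1.17 ± 0.09. MHC class II genes were lower for 6 of 11 and higher for 0 (7 and 0 over the list alone), with H2-Eb2 (-2.51 ± 0.19) and Ciita (-1.98 ± 0.12). Macrophage signature genes were lower for 6 of 35 and higher for 1 (14 and 1 over the list alone), with Lyz2 at -3.15 ± 0.80, whose call was lost when the 8 arrays were fitted alone. Maturation genes were higher for 9 of 27 and lower for 1 (12 and 2 over the list alone), with H2-M2 as the lower one (-2.53 ± 0.22). Interferon-stimulated genes were higher for 9 of 29 and lower for 5 (10 and 5 over the list alone), with Irf7 (1.29 ± 0.15) against Rtp4 (-1.07 ± 0.23). B cell markers were lower in CD8α+ cDC for 11 of 14 and higher for 0 (13 and 0 over the list alone, median -1.46), such as Bank1 (-2.25 ± 0.41). Plasma cell markers had 2 of 7 lower, plasmacytoid DC markers 4 of 9 lower and T cell markers 1 of 12 higher (list adjusted p = 0.0329, 0.0106 and 0.0233, lost at adjusted p = 0.428, adjusted p = 0.155 and adjusted p = 0.396 with an estimated correlation).

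Camera called these lists at adjusted p = 1.91e-09 (cDC1), 1.47e-09 (cDC2), 1.34e-08 (MHC class I), 2.76e-07 (MHC class II), 0.00033 (macrophage), 0.00238 (maturation), 0.0147 (interferon-stimulated) and 3.02e-09 (B cell). The cDC1, cDC2 and MHC class I lists were lost at adjusted p = 0.0689 each with an estimated correlation, and MHC class II at adjusted p = 0.0908. Macrophage, maturation, interferon-stimulated and B cell lists were lost at adjusted p = 0.26, adjusted p = 0.268, adjusted p = 0.338 and adjusted p = 0.244 with an estimated correlation. Of 19938 genes 2473 were called, 1141 higher and 1332 lower in CD8α+ cDC, and 743 of them differed by at least 2-fold. Of all genes tested, 3380 did not overlap between the arrays (3.57% by chance).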

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

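The tests of array sets processed apart and of an offset between array sets, the latter with its limits, were chosen after the results they measure had been seen, and so was the comparison of both cDC groups after R848.

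The number of genes whose response to R848 differed between CD8α+ and CD11b+ cDC (4801) stood out because the difference itself was tested, although the untreated arrays of both lay in different array sets. By the same test the response of CD8α+ cDC was higher for Gzma (6.41), Spib (4.82), Mt2 (4.67), Cd7 (4.25), Thy1 (3.76), Slc2a6 (3.67), Lgmn (3.67), Cd3g (3.65) and Nkg7 (3.65). It was lower for Cxcr3 (-4.42), Sdad1 (-3.14), Itga8 (-2.99), Tlr12 (-2.97), Cadm1 (-2.84), P2ry14 (-2.81), Igf2r (-2.73), Apol7c (-2.67) and Prkar2b (-2.65). Armc4 was lower by the same test (-4.38), but a second probe set of Armc4 gave 0.21. Spib was lower in untreated CD8α+ than in untreated CD11b+ cDC by about the size of its difference of responses. That difference thus rests on the untreated CD8α+ arrays, whose group and array set cannot be told apart. Olig1 was higher (4.77), with levels of 9.14 in untreated CD11b+, 4.44 in untreated CD8α+, 4.77 in R848 CD11b+ and 4.84 in R848 CD8α+ arrays. Its difference thus rests on the untreated CD11b+ arrays, and these levels alone cannot tell their group from their array set. Among gene lists the median response of CD8α+ minus CD11b+ cDC was 1.32 for maturation and co-stimulation, -1.75 for the cDC1 signature, -0.54 for MHC class II presentation and 1.66 for T cell markers. The cDC1 list started at a higher mean in untreated CD8α+ (9.21) than in untreated CD11b+ cDC (6.642).

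Of 84 list values tested for single arrays far from the others of their group, 3 stood apart, and chance picks about 1 in 20 groups. They were the mean of apoptotic cell uptake genes (5.68) and of dissociation and immediate early genes (7.86) in CD8α+ R848 replicate 2, and the mean of glucocorticoid-induced genes (6.46) in CD8α+ R848 replicate 1.

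Regrouping the arrays argued against randomly drawn groups for most counts, since 1 split, the real one, called as many genes. For LysoMac against cDC this was 6187 against at most 2690 in any other of 100 splits, for CD8α+ against CD11b+ cDC 6895 against 3378 of 56 splits, and for both cDC groups after R848 2473 against 334 of 56. For the responses it was 6779 against 3452 of 56 splits in CD11b+ cDC, 9477 against 2315 of 56 in CD8α+ cDC, and 4801 against 4166 of 100 for their difference. In CD8α+ against CD11b+ cDC and in both responses, the real split also parted the array sets. Regrouping cannot tell the group from the set there. Sets also enter LysoMac against cDC and the difference of responses, so only the comparison after R848 is free of this limit. For DN against CD11b+ cDC chance could not be excluded, as 5 of 56 splits called at least the real 704 genes, and the highest other called 1894. For TIM-4+ against TIM-4- LysoMac (73, highest other 1) and DN against CD8α+ cDC (6166, highest other 0) the 10 splits were too few for a share under 0.05.

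Interferon-stimulated genes were higher in both R848 groups, and all R848 arrays lay in a different array set from the untreated ones. A general shift of signals between array sets is argued against. After cyclic loess the list's median change was 1.659 in CD11b+ and 2.191 in CD8α+ cDC. The upper bound of the central range of 10000 random lists was at most 0.402. Random lists hold genes that need not vary together. The test thus cannot argue against a set difference that moved interferon genes as a group. Other cells among the sorted cells remain possible, since the B cell marker list in CD11b+ cDC changed by 1.356 times the median of the interferon-stimulated genes, against 0.497 times in CD8α+ cDC. The plasma cell list gave 0.882 and 0.244 times. These ratios rest on different members in each subset. Over the 6 B cell genes measured in all array sets, the mean rose from 5.832 to 7.68 in CD11b+ and from 4.695 to 6.407 in CD8α+ cDC. The treatment is the biological explanation that the design gives, and no array set held both treated and untreated arrays to separate it from the set.

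In the deposited scaling most genes that differed were lower in CD8α+ than in CD11b+ cDC before treatment, and the groups lay in different array sets. An offset between the sets is in line with 72.086% of 1021 negative control genes being lower in CD8α+ cDC (median -0.11). That share does not single out the sets, since DN against CD11b+ cDC, inside 1 set, gave 71.126% (median -0.05). The size of the shift says more. In the R848 response of CD8α+ cDC 11.072% of the control genes were lower (median 0.208, against 0.184 for all genes). In the difference of responses 22.037% were lower (median 0.144), and in DN against CD8α+ cDC 38.492% (median 0.046). Inside 1 set the medians lay between -0.052 and 0.045. An offset of the untreated CD8α+ set thus remains possible in all comparisons that use it. Dim genes alone are argued against, as 77.803% of called genes were lower among brighter genes. Transcripts per cell cannot be read from these values, because 2 to 20 ng of RNA were amplified and the signals were computed with RMA. After cyclic loess the split was 2638 higher and 2675 lower. The direction turned with the scaling, to 3392 higher and 2112 lower after shifts to a common median. Quantile normalization gave 2787 higher and 2575 lower.

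Stromal, endothelial and some epithelial markers were higher in DN than in CD11b+ cDC, with Sparc at a mean of 9.54 and 4.57. The presence of stromal or endothelial cells in the CD11c-high, MHCII+ gate is consistent with 66.667% of a second panel of 21 such genes being higher in every DN array than in every CD11b+ array (1.79% by chance). A second panel of 19 epithelial genes gave 5.2632% by the same criterion, with 2 genes called higher, 0 lower and a median of 0.376. This cannot decide on epithelial cells, because the first epithelial list itself gave only 6.6667% of 15 members. Epithelial markers also varied among the untreated CD11b+ arrays (SD of the list mean 0.774), which makes a complete separation hard to reach. Separate processing of CD11b+ replicates 4 and 5 is argued against by a median of the stromal list of 0.724 without them and 0.783 with them. Whether DN cDC themselves could express these genes stays open, because sorted mixtures and single cells cannot be told apart on these arrays.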

How the results depend on the processing

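With calls limited to 2-fold, counts were 1155 (LysoMac against cDC), 34 (TIM-4), 1026 (CD8α+ against CD11b+), 190 (DN against CD11b+), 1285 (DN against CD8α+), 1333 (R848, CD11b+), 1915 (R848, CD8α+), 1098 (difference of responses) and 743 (after R848, chosen after seeing the data), fewer by construction. With only the compared arrays fitted, counts were 27 (TIM-4) and 326 (DN against CD11b+), with fewer arrays to estimate the spread. With brighter genes alone, so fewer genes tested, they were 4343 (CD8α+ against CD11b+), 5589 (R848, CD8α+) and 3140 (difference of responses). Shifts to a common median gave 3118 for the difference of responses, and the cause was not tested. Chosen after seeing the data, counts with rows in the deposited order were 22455, 173, 25736, 1200, 25468, 25758, 25409 and 24613 in the order above up to the difference of responses. In the 6 of these comparisons across array sets, the rows of different sets then hold different genes, while TIM-4 and DN against CD11b+ lie inside 1 set and were tested on 28939 rows instead of 16549 genes. DN against CD11b+ replicates 4 and 5 alone, also chosen after seeing the data, gave 4081, and the cause was not tested. The position of DN cDC was 0.922 on the 100 most different genes and 0.969 after quantile normalization (chosen after seeing the data), and the cause was not tested. Gene list calls went from 74 to 18 with a correlation estimated per list, which allows for genes that vary together. With 1 array left out, counts ranged over 5551 to 6223 (LysoMac), 43 to 80 (TIM-4, 43 without TIM-4- replicate 1 and 44 without replicate 3), 5510 to 6704 (CD8α+ against CD11b+), 464 to 898 (DN against CD11b+, 464 without DN replicate 2), 5112 to 5492 (DN against CD8α+), 5586 to 6642 and 7960 to 9186 (R848, CD11b+ and CD8α+), 3891 to 4841 (difference) and 1778 to 2355 (after R848). The shared responses ranged over 2765 to 3254, their correlation over 0.611 to 0.659, and the position over 0.927 to 0.967 (0.93 without CD11b+ replicate 1, 0.927 without replicate 2). Named genes kept direction and call in 5960 of 6070 values, 82 lost the call, 10 gained it and 18 changed sign, each of a sort marker that was not called, where the cause was not tested. These were Itgax in LysoMac against cDC (-0.036 with a common median, -0.004 with quantile normalization) and in CD8α+ against CD11b+ cDC (0.002 with a common median, 0.024 with cyclic loess, 0.108 with quantile normalization), Cd4 in the CD11b+ response (0.115 with cyclic loess, 0.044 with quantile normalization, -0.202 to 0.023 with 1 array left out), Itgam after R848 (-0.049 with array weights, -0.002 with quantile normalization, -0.184 to 0.116 with 1 left out), Bst2 in DN against CD11b+ cDC (0.146 with CD11b+ replicates 1 to 3, -0.231 to 0.014 with 1 left out), and Bst2 (-0.011 to 0.191) and Sirpa (-0.033 to 0.089) between LysoMac groups with 1 left out. Quantile normalization, replicates 1 to 3 and all settings after R848 were chosen after seeing the data. With a replicate block, counts were 6085, 67, 6478, 474, 6282, 6687, 8781, 4035 and 2251 in the order above, and 284 of 306 gene list tests stayed on the same side of the threshold, 7 calls were lost and 15 gained. Over all group pairs, 11 of 65 same-number correlations were over 0.1 (-0.236 to 0.176). In 2 of 21 group pairs every array correlated best with its own number, and both lay inside the untreated set of CD11b+, DN and LysoMac arrays. Inside that set, mean same-number correlations were -0.008 to 0.111 per group pair, against -0.054 to 0.002 for other numbers. For DN with CD11b+ cDC they were 0.08 against -0.02, and for both LysoMac groups 0.072 against -0.036. A weak pairing by number thus cannot be excluded in that set. Of the dimmest 25% of genes, those called inside 1 array set were 0.0243% for TIM-4, 1.89% for DN against CD11b+ cDC, 0.762% after R848 and 6.48% for LysoMac against CD11b+ and DN cDC. Across sets it was 20.2% for LysoMac, 37.5% and 28.0% for CD8α+ against CD11b+ and DN cDC, 24.3% and 56.7% for the responses of CD11b+ and CD8α+ cDC and 23.7% for their difference.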

Other observations

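Genes of retinoic acid metabolism and IgA-related factors, a list that covers the imprinting of gut lymphocytes, had members that changed in both R848 responses. Aldh1a2, the enzyme that makes retinoic acid, rose by 2.09 ± 0.17 in CD11b+ (3 against 5 arrays) and 2.59 ± 0.17 in CD8α+ cDC (5 against 3 arrays), and was lower in LysoMac than in cDC (-2.59 ± 0.12). Ido1, which degrades tryptophan, rose by 1.14 ± 0.19 and 0.91 ± 0.19, and the receptor Rara fell by 1.25 ± 0.14 and 1.68 ± 0.14. The list had 6 of 11 members higher and 2 lower in CD11b+ cDC (list adjusted p = 0.305) and 5 of 12 higher and 5 lower in CD8α+ cDC (list adjusted p = 0.328). The inflammasome sensor Nlrp3 fell in both responses (-2.60 ± 0.18 and -1.38 ± 0.18), as did the cytokine Il18 (-1.63 ± 0.18 and -1.37 ± 0.18). Ido1 and Il18 in CD8α+ cDC fell outside the rule for named genes and were chosen after their values were seen.

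NK cell and ILC markers were lower in LysoMac than in CD11b+ and DN cDC for 6 of 9 members and higher for 0 (7 and 0 over the list alone, list adjusted p = 0.000282, and adjusted p = 0.0302 with an estimated correlation). They included Il7r (-3.29 ± 0.14), the activating receptor Klrk1 (-2.24 ± 0.15) and the transcription factor Tbx21 (-2.12 ± 0.08). After R848, genes of the unfolded protein response were lower in CD8α+ than in CD11b+ cDC for 3 of 17 members and higher for 1 (7 and 1 over the list alone, list adjusted p = 0.0185, and adjusted p = 0.448 with an estimated correlation), such as the disulfide isomerase Pdia6 (-0.88 ± 0.21, a call lost when the 8 arrays were fitted alone).

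Among the 5 untreated CD11b+ arrays, replicates 4 and 5 stood apart from replicates 1 to 3, a contrast chosen after seeing the data. Of 16549 genes 3385 were called, 2266 higher and 1119 lower in replicates 4 and 5, and 213 by at least 2-fold. The chemokine Cxcl2 (-2.82 ± 0.57) and the goblet cell peptide Tff3 (-2.49 ± 0.77) were lower, and the metallothionein Mt2 (1.68 ± 0.41) and Nkg7 (1.55 ± 0.35) were higher.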
